A study of Mus musculus with 6 samples.

How the data were processed

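The series holds RNA sequencing of microglia sorted from mouse brain, 3 libraries labelled WT and 3 labelled KO. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.1a, HOMER 4.11.1 and DESeq2 1.26.0 with the mm10/GRCm38 genome; the notes give no order or parameters. Whether counting used the strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

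The deposited table has 55421 rows, 1 per gene, with a signal for each of 6 libraries that the authors scaled so that every column sums to 34360040 to 34360054. The deposited signal is not a raw count. Within each column, 100% of the values above 0 lay within 0.1 of a whole multiple of 1 step, 0.445 to 0.603 by column, so the whole reads behind them could be recovered. The recovered totals were 67839380, 77199936 and 56988261 reads for WT A, WT B and WT C and 75013004, 61977830 and 73302092 for KO A, KO B and KO C. A count of 0 leaves room for up to 3 reads, or 1.34 to 1.81 on the deposited scale. The deposited table also holds the log2 fold change, p-value and adjusted p-value of the authors' own comparison, and a deposited list of 503 genes; every listed gene had an adjusted p under 0.05, an absolute log2 fold change over 1.5 and a mean over 100 in the authors' deposited table. There, 6325 genes have an adjusted p under 0.05, 3226 higher and 3099 lower. Of the rows, 54884 (99.03%) name a transcript of GENCODE M21 with the same chromosome, start, end and strand, counted from 1.

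The columns are named Control and Treatment with the letters A, B and C. Control was taken as WT and Treatment as KO from the group names alone. The letters match no number in the labels. In replicate comparisons within groups no libraries were alike to within sampling noise (chi-square per gene of 27.8 or more). The letters were checked for pairing: over 11588 genes with a mean above 100, the deviations from the group mean correlated at 0.61 for A, 0.20 for B and 0.30 for C between the groups. All 3 exceeded 0.1, so the letters were treated as pairing the libraries; this rests on the column letters and that check, with nothing in the labels behind it. The fit without the pairing was kept as the main one, as fixed before the data were examined.

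The design had fixed edgeR with trimmed-mean (TMM) factors for raw counts, and a test on normalised values as the case without them. Because the files held normalised values, the latter was used. One row per symbol was kept, that with the highest mean, which left out 117 rows. Genes with a mean above 1 over the 6 libraries were tested with limma 3.58.1 (trend, R 4.3.3) on log2(value + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on that scale understate the change of low genes; folds given as such are ratios of group means. Gene lists (16 of pathways, 13 of cell type markers) were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted within each family. Genes named in the text are Qk and Cx3cr1, the 12 largest rises and the 12 largest falls among called genes with a mean above the median of 120.9, groups that do not overlap and a symbol that is not a gene model name, and up to 4 members per list with the smallest p. The results of 1 of the 16 lists and of some single genes are not reported here. Members named for not passing, for an exception or as counterparts were chosen after their values were seen.

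On data simulated for the comparison of KO against WT with 22398 genes tested, limma recovered 33.3%, 43.8% and 75.0% of genes changed 1.5-fold, 2-fold and 4-fold, and 11.8% of its calls were false. The changed genes tested numbered 63, 64 and 64, far fewer than the 7781 called in the data. The adjusted threshold depends on the share of changed genes, so these percentages are not the power of the real comparison. With no change simulated, at most 4 genes were called in any of 20 draws and 0 draws had a called list; the simulated genes varied independently, so the draws do not test correlation between genes. The motif comparison was tested on the fold changes of 9129 genes, shuffled among them: an added shift of -0.1 was found as -0.088 (permutation p = 0.004), and no shift as -0.021 (permutation p = 0.4765). Shuffling removes any link of fold change with length or level, so the matching itself was not tested.

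Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter at the median, all rows, each library left out, stricter thresholds, other list tests, and a block. Chosen after seeing the data were TMM factors on the normalised values, edgeR 4.0.16 with TMM, RLE or upper-quartile factors, DESeq2 1.42.0 and limma-voom on the recovered reads, edgeR on fragments, and the use of the column letters for the block. Of these, edgeR with TMM factors was the test fixed for raw counts, and only its use on recovered reads was chosen afterwards. Symbol families were also chosen afterwards; they were compared with Fisher's exact test among 12896 genes with a mean above 10. The 3' untranslated regions came from GENCODE M21 (Python 3.11.15). Reads per exon, splice junctions and isoforms were not analysed here.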

Results

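RNA was measured by sequencing in microglia, the resident macrophages of the brain, that had been sorted by flow cytometry on the surface proteins CD45 and CD11b. The animals were C57BL/6 mice of 4 to 5 weeks. The 3 libraries labelled WT came from mice whose Qk gene carried loxP sites on both alleles without a Cre gene. The 3 libraries labelled KO came from mice with the same Qk alleles and a Cre-estrogen receptor fusion under control of the Cx3cr1 locus. Qk encodes QKI, an RNA-binding protein that acts in splicing and in the stability of messenger RNA. The groups thus differed in the Cre allele as well as in the intended loss of QKI. The labels give no tamoxifen treatment, on which the activity of such a fusion depends. The deposited values summed to 34360040 to 34360054 normalised reads per library. The whole reads recovered behind them numbered 56988261 to 77199936 per library. Nothing in the labels said whether the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries.

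The targeted gene was measured first. Qk was higher, not lower, in the libraries labelled KO. Its level was 11632 ± 800 normalised reads in the libraries labelled WT (SD, n = 3) and 24768 ± 1073 in those labelled KO (SD, n = 3). This was a 2.13-fold rise, with a log2 fold change of 1.09 (SE 0.08, adjusted p = 2.45e-06, limma), and all 3 libraries labelled KO lay above all 3 labelled WT. Qk lies on the minus strand of chromosome 17 at 10206551 to 10319854 (GRCm38). The deposited value is given for 1 transcript and does not show whether an exon was deleted; reads per exon were not analysed here. The rise is opposite to a loss of the transcript, but it neither shows nor excludes the deletion of an exon. Every direction below is that of the libraries labelled KO against those labelled WT. Cx3cr1, the fractalkine receptor gene that carries the Cre, was 4.22-fold lower. It had 246161 ± 11084 normalised reads in the libraries labelled WT and 58308 ± 4848 in those labelled KO (SD, n = 3 each), a log2 fold change of -2.08 (SE 0.10, adjusted p = 1.81e-07). Cx3cr1 lies on the minus strand of chromosome 9 at 120048683 to 120069879.

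**Figure D1:**
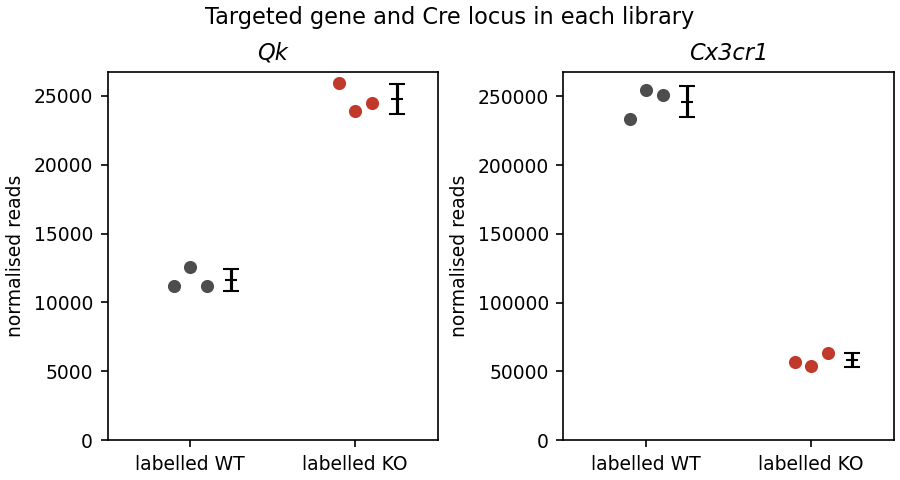
Normalised reads of Qk and Cx3cr1 in each of the 6 libraries; points are libraries, and the bar beside them is the mean with its SD (n = 3). The Qk values of the libraries labelled KO, 23859 to 25951, lie above those labelled WT, 11160 to 12556, and the Cx3cr1 values lie below.

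The comparison asked which transcripts of microglia differed with the genotype aimed at QKI. Of 22472 genes tested, 7781 passed an adjusted p of 0.05, of which 2529 were higher and 5252 lower in the libraries labelled KO. The split depended on the scaling. With trimmed-mean (TMM) factors, a choice made after the data were seen, 6904 of 22461 genes passed, 3452 higher and 3452 lower. The share of higher genes was 32.5% with the deposited scaling. The deposited scaling set the median log2 fold change of all tested genes at -0.15 and the TMM factors set it at -0.02, so a small fall of a gene is to be read against that shift. Among the called genes, 2936 had an absolute log2 fold change of at least 1, with 1199 higher and 1737 lower. The first principal component held 85.5% of the variance and parted the 2 groups. Over all 22472 tested genes the groups did not overlap for 10760 (47.9%), where chance alone gives 10% for 3 libraries against 3, and 9889 genes had an unadjusted p under 0.05. The authors' deposited table lists 503 genes, 343 higher and 160 lower; all 503 passed here in the same direction.

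**Figure D2:**
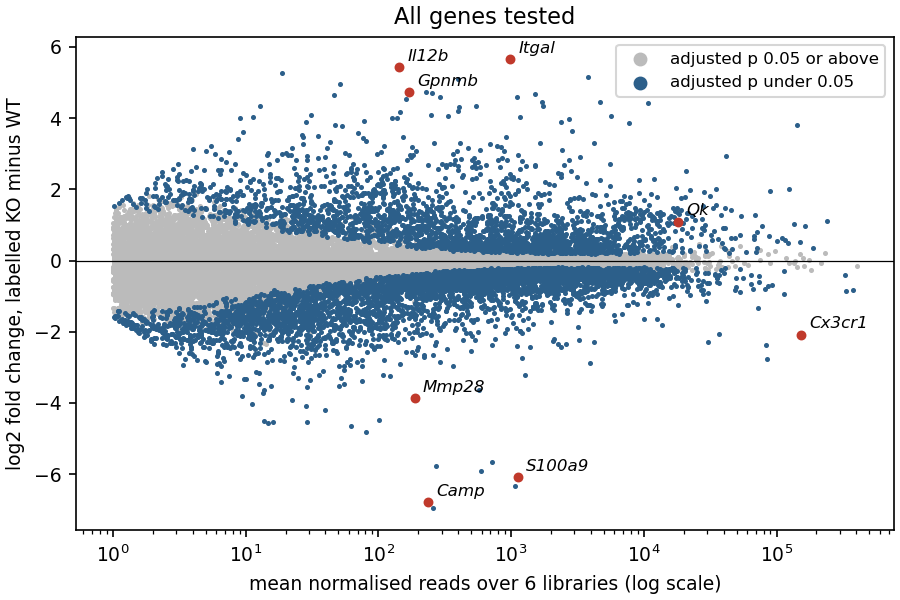
Log2 fold change (labelled KO minus labelled WT) against the mean normalised reads over 6 libraries (log scale) for the 22472 genes tested. Blue points are the 7781 genes with an adjusted p under 0.05, grey points the others, and red points are named genes such as Itgal at 5.66 and Camp at -6.78.

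The 12 largest rises were taken among called genes above the median level whose groups did not overlap. Itgal, which encodes the alpha chain of the integrin LFA-1, went from 37.8 ± 8.24 to 1930 ± 112 normalised reads (SD, n = 3 each), a log2 fold change of 5.66 (SE 0.16, adjusted p = 1.91e-08). Il12b, the p40 subunit of interleukins 12 and 23, rose by 5.43 (SE 0.54) and by 4.66 without WT C, and Ptgs2, the inducible cyclooxygenase, rose by 5.16 (SE 0.16). Nr4a3, an orphan nuclear receptor induced early after stimulation, rose by 5.10 (SE 0.37); its level in the libraries labelled KO varied widely, 778 ± 491. Gpnmb, a membrane glycoprotein of activated phagocytes, went from 11.4 ± 1.69 to 331 ± 69.7. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, went from 440 ± 193 to 8979 ± 927, and the early activation antigen gene Cd69 from 22.5 ± 1.79 to 566 ± 73.5. The chemokine gene Ccl5 and the interferon-induced genes Oas1g, Oas2, Oas3 and Ifi207 completed the set, with log2 fold changes of 4.70, 4.74, 4.58, 4.53 and 4.67. Oas1g, Oas2 and Oas3 lie in 1 cluster of related genes on chromosome 5, where similar sequence could move reads between them.

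The 12 largest falls under the same rule had 7 genes of neutrophils, monocytes or their precursors among them. Chil3, Camp, Ngp, S100a9, Ltf, Lcn2 and S100a8, which encode granule, secreted or cytosolic proteins of those cells, had log2 fold changes from -6.95 to -5.67. Their levels in the libraries labelled WT varied almost as much as their mean: S100a9 had 2230 ± 2150 normalised reads there and 22.6 ± 10.3 in the libraries labelled KO (SD, n = 3 each). Library WT C alone held 4626.3 of S100a9, against 1582.3 in WT A and 467.8 in WT B. Without WT C the log2 fold changes of the 7 genes ran from -6.18 to -4.92, and without WT B from -7.69 to -6.42. Chil3 and Camp, at 2 ± 0.709 and 1.92 ± 0.853 in the libraries labelled KO, lay near the limit that a count of 0 allows, 1.37 to 1.66, and limma-voom on the recovered reads did not call them (adjusted p = 0.059 and adjusted p = 0.0812). The other 5 genes varied less. Mmp28, a matrix metalloproteinase gene, went from 351 ± 44.4 to 23.8 ± 7.24, and Pde2a, a cyclic nucleotide phosphodiesterase gene, from 1070 ± 165 to 84.9 ± 8.24. Cd276, an immune checkpoint ligand gene, went from 2309 ± 209 to 252 ± 47, and Adamtsl2, a gene of an extracellular matrix protein, from 259 ± 11 to 33.6 ± 4.23. Slc5a10, a sugar transporter gene, was 9.66-fold lower.

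Markers of other cells in the brain moved with the groups. Of 11 tested neutrophil markers, 9 were lower and 0 higher, and 11 lower when adjusted over the list alone (median log2 fold change -5.67, camera adjusted p = 0.00108; adjusted p = 0.673 with an estimated correlation). Of 14 neuronal markers 13 were lower, such as Snap25, a synaptic vesicle fusion gene, with 38.5 ± 4.37 against 12.7 ± 1.72 (camera adjusted p = 0.000589; 0.16 as adjusted p with an estimated correlation). Astrocyte markers were lower in 11 of 12, among them the glutamate transporter gene Slc1a3, 5261 ± 650 against 2223 ± 261, with a camera adjusted p = 0.0034 (adjusted p = 0.673 with an estimated correlation). Pericyte and fibroblast markers were lower in 9 of 12 (camera adjusted p = 0.0244; adjusted p = 0.673 with an estimated correlation), a call lost without KO replicate C (adjusted p = 0.0654). Endothelial markers were lower in 8 of 12 (camera adjusted p = 0.065), and the list passed with TMM factors (adjusted p = 0.0159) or without WT replicate A, WT replicate B or KO replicate B (adjusted p = 0.0312, 0.013 and 0.0489). Oligodendrocyte markers were lower in 8 of 12 and higher in 1, Trf (10 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.0883), and the list passed with TMM factors (adjusted p = 0.0344) or without WT replicate B or WT replicate C (adjusted p = 0.013 and 0.0192). Trf, the transferrin gene, stood at 53900 normalised reads in the libraries labelled WT and rose by 0.25. Markers of oligodendrocyte precursors were lower in 4 of 8, Sox10, Olig1, Olig2 and Cspg4, and did not pass as a list (adjusted p = 0.259; 0.0406 as adjusted p with edgeR). Without WT C the log2 fold change of Sox10 went from -2.32 to -1.59, and Olig2 was no longer called without any 1 of WT A, WT C, KO A, KO B or KO C.

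Library WT C held the highest sum of each of these marker lists. Its sums were 883.3 normalised reads for oligodendrocyte precursors (211.0 and 305.4 in WT B and WT A), 4650.4 for pericytes and fibroblasts (1599.2 and 2005.7 in WT B and WT A), 4869.3 for endothelial cells (2719.8 and 2867.2 in WT A and WT B) and 11614.3 for astrocytes (7296.6 and 8656.0 in WT B and WT A). The neuronal sum differed less, 838.1 against 691.4 in WT A and 702.8 in WT B. Without WT C the median log2 fold change went from -1.25 to -0.92 for astrocytes, from -1.95 to -1.29 for oligodendrocytes, from -1.35 to -0.97 for their precursors, from -1.55 to -1.01 for endothelial cells, from -1.28 to -0.81 for pericytes and fibroblasts and from -1.54 to -1.50 for neurons. The neutrophil median went from -5.67 to -4.92. Among genes above the median level the astrocyte and pericyte lists did not pass (adjusted p = 0.0948 and adjusted p = 0.175). For neurons, astrocytes, endothelial cells, pericytes and oligodendrocyte precursors the counts were the same when adjusted over the list alone. Over the 70 tested markers of neurons, glia and vessels the median log2 fold change was -1.42, -1.29 with TMM factors and -1.03 without WT C, where 43 were lower and 0 higher. With all libraries 53 of the 70 were lower and 1 higher, and with TMM factors 44 and 1. By list, the lower markers with TMM factors were 10 for neurons, 8 for astrocytes, 7 for endothelial cells and 7 for pericytes and fibroblasts. They were 8 for oligodendrocytes and 4 for their precursors, as with the deposited scaling.

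Monocyte markers were mixed: 6 of 11 were lower and 1 higher (the same counts when adjusted over the list alone; camera adjusted p = 0.065). The list passed as lower with TMM factors (adjusted p = 0.0159) and without WT replicate B or WT replicate C (adjusted p = 0.013 and 0.04). The exception, Ms4a4c, went from 49.7 ± 21.5 to 477 ± 70.1. Markers of border-associated macrophages, which line the vessels and meninges, were higher in 6 of 12 and lower in 1, Stab1 (7 and 1 when adjusted over the list alone), with a median of 0.85. The list passed by camera (adjusted p = 0.00534), and not with an estimated correlation (adjusted p = 0.673) or among genes above the median level (adjusted p = 0.183). The folate receptor gene Folr2 rose from 44.2 ± 12.3 to 176 ± 35.9, and the mannose receptor gene Mrc1 from 967 ± 89 to 2085 ± 635. Few markers of lymphocytes reached the level tested: of 5 for T cells Cd5 was higher and Lck lower, of 5 for B cells Cd22 was higher and Ebf1 and Cd79b lower, and of 2 for NK cells Klrb1c was lower (both when adjusted over the list alone). The T cell gene Cd4 passed only without WT A. The calls of Ebf1 and Klrb1c, at 16.6 and 6.86 normalised reads in the libraries labelled WT, were lost when single libraries of either group were left out, and that of Ebf1 also with TMM factors. Of 6 tested erythroid markers, from a list of 7, 0 passed by limma, 0 with TMM factors, and 0 had an unadjusted p under 0.05. Camera called none of these 4 lists (adjusted p = 0.897, 0.425, 0.118 and 0.884 in that order).

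**Figure D3:**
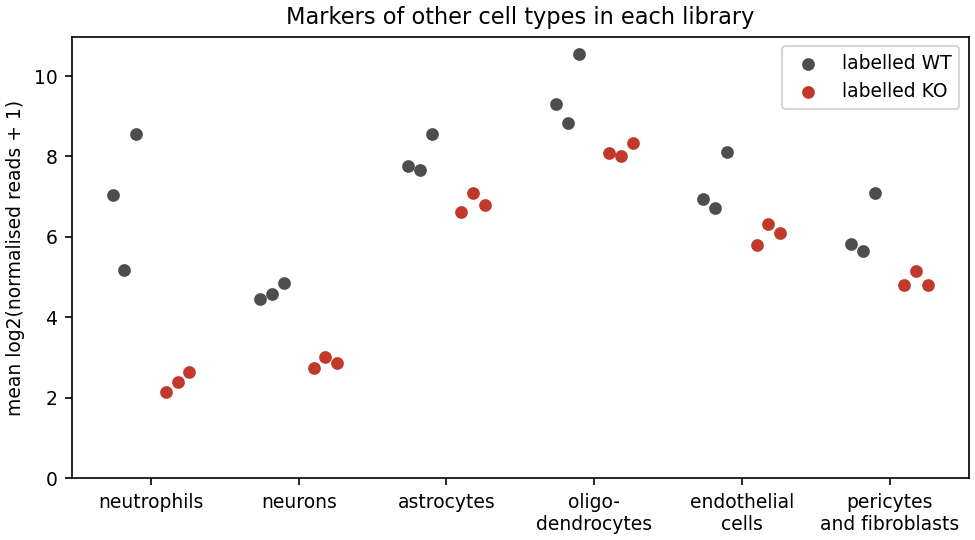
Mean log2(normalised reads + 1) of the tested markers of 6 other cell types in each library; each point is 1 library (grey, labelled WT; red, labelled KO). Neutrophil markers range from 5.18 to 8.55 in the libraries labelled WT and from 2.15 to 2.64 in those labelled KO.

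Genes that mark resting microglia fell. Of 28 homeostatic genes, 23 were lower and 0 higher (24 lower when adjusted over the list alone), with a median log2 fold change of -0.82; with TMM factors 18 were lower and 0 higher. The list passed at a camera adjusted p = 9.87e-10 and not with an estimated correlation (adjusted p = 0.148). P2ry12, a purinergic receptor gene of microglial processes, went from 147375 ± 17291 to 21842 ± 3104 normalised reads (SD, n = 3 each), 6.75-fold lower. Sparc, a matrix glycoprotein gene, went from 139038 ± 2536 to 27001 ± 2239, and the fructose transporter gene Slc2a5 from 21284 ± 555 to 6064 ± 184. Siglech was -0.17 and Itgb5 0.02 on the log2 scale, and neither passed.

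Genes known from microglia around amyloid plaques and other lesions moved mostly the opposite way. Of 28 disease-associated genes 18 were higher and 6 lower (18 and 7 when adjusted over the list alone), and with TMM factors 19 and 2. The camera adjusted p = 1.07e-07 was lost with an estimated correlation (adjusted p = 0.252). Apoe, the main lipoprotein of the brain, rose 13.7-fold, from 19196 ± 5261 to 263815 ± 6164. Axl, a receptor tyrosine kinase that binds dying cells, rose 21.5-fold, from 951 ± 124 to 20404 ± 984, with a log2 fold change of 4.43 (SE 0.09, adjusted p = 3.5e-09). Spp1, the osteopontin gene, rose 6.23-fold, and Lilrb4a, an inhibitory receptor gene, 5.04-fold. Trem2, the receptor gene of the same programme, had a log2 fold change of -0.24 and did not pass, while Ccl6 was 2.39-fold and Ank 1.48-fold lower.

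Interferon response genes rose almost throughout. Of 38 genes 36 were higher and 0 lower (37 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 2.26. The camera adjusted p = 9.24e-33 compares with an adjusted p = 0.126 with an estimated correlation. Oas2, an antiviral 2'-5' oligoadenylate synthetase gene, went from 88.7 ± 14.7 to 2130 ± 105. Cxcl10, an interferon-induced chemokine gene, rose 12.5-fold, from 428 ± 66 to 5339 ± 631. Ifi204 rose 15.4-fold and Usp18, the negative regulator of interferon signalling, 7.14-fold. Gbp7, at -0.28, and Slfn8, at 0.24, did not pass, and with TMM factors Slfn8 passed at 0.38.

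Inflammatory genes downstream of NF-kB rose too. Of 29 genes 24 were higher and 0 lower (24 and 1 when adjusted over the list alone), with a median of 1.55 and a camera adjusted p = 2.26e-16 (adjusted p = 0.126 with an estimated correlation). Il1b, the interleukin 1 beta gene, rose 15.0-fold, from 974 ± 138 to 14574 ± 4299, and the chemokine gene Ccl3 4.00-fold, from 13952 ± 2382 to 55791 ± 1257. Ccl12 rose 5.04-fold. Il6 was 0.00 and Nfkb1 0.14 on the log2 scale, and neither passed, while with TMM factors Nfkb1 passed at 0.28. In the list of antigen presentation 12 of 21 genes were higher and 1, Cd86, lower (14 and 1 when adjusted over the list alone; camera adjusted p = 7.62e-09, adjusted p = 0.126 with an estimated correlation). Among the rises were class I genes: H2-K1 went from 17870 ± 296 to 52585 ± 1360, H2-D1 from 17606 ± 960 to 49329 ± 4119, and Nlrc5, the activator of class I transcription, rose 4.77-fold. H2-K1, H2-D1 and H2-Q4 are close copies, so reads may be divided between them with error. The class II genes H2-Aa, H2-Eb1 and H2-Ab1, at 0.36, 0.38 and 0.42, did not pass.

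Genes of cell division were higher in 28 of 35 and lower in 0, counts that were equal when adjusted over the list alone. Their median was 1.66 and the camera adjusted p = 7.59e-15, against an adjusted p = 0.334 with an estimated correlation. Mki67, which encodes the proliferation antigen Ki-67, went from 334 ± 130 to 1449 ± 302, Top2a, the DNA topoisomerase gene, from 299 ± 89 to 1182 ± 334, and the mitotic kinase gene Aurkb from 46.6 ± 12.8 to 221 ± 36.6. The replication genes Mcm3, Mcm4 and Mcm7 were 0.11, 0.19 and 0.01 on the log2 scale and did not pass, while with TMM factors Mcm4 passed at 0.33.

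Immediate early genes, which also respond to the dissociation of tissue, were higher in 19 of 27 and lower in 1, Jund (the same counts when adjusted over the list alone), with a median of 0.68. The camera adjusted p = 8.19e-10 was lost with an estimated correlation (adjusted p = 0.126). Nr4a1 rose 7.69-fold, from 9579 ± 2406 to 73618 ± 18638, Egr3 6.63-fold and Dusp2 5.41-fold. The heat shock genes Hspa1a and Hspa1b were both 0.14 and did not pass, and Jund fell by 0.50. The share of mitochondrially encoded reads was 0.66% to 0.94% in the libraries labelled WT and 1.22% to 1.47% in those labelled KO.

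**Figure D4:**
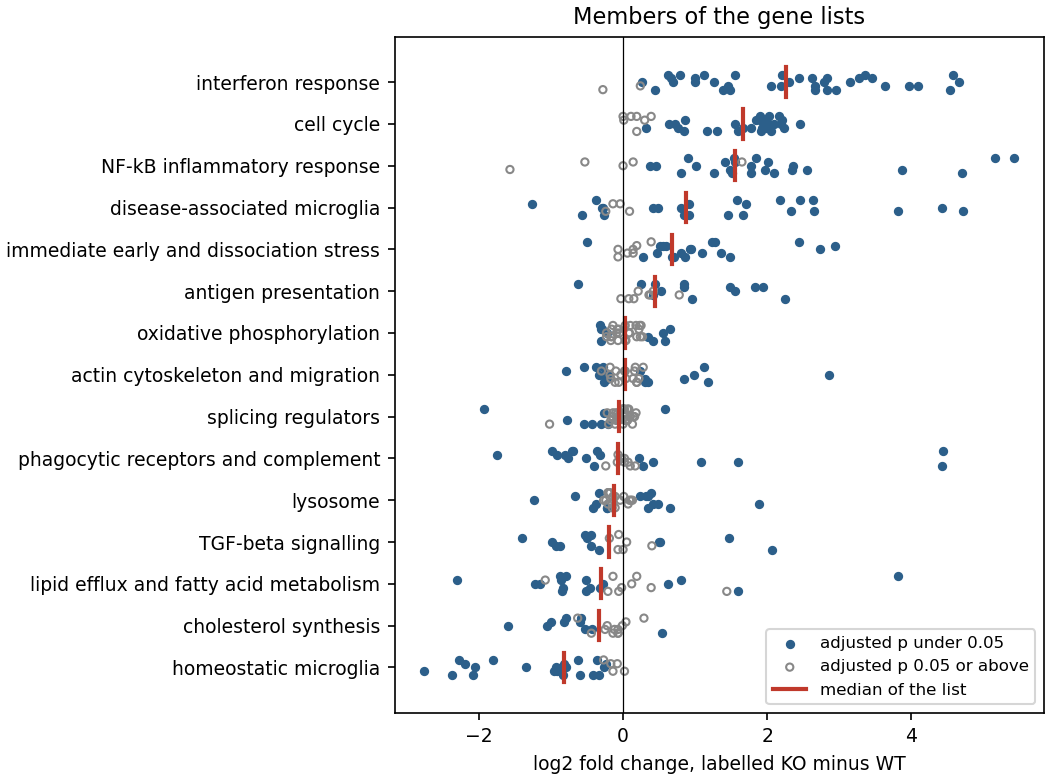
Log2 fold change (labelled KO minus labelled WT) of the tested members of the gene lists; filled points have an adjusted p under 0.05, open points do not, and the red bar is the median. The interferon response list has the highest median, 2.26, and the homeostatic list the lowest, -0.82.

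Lipid genes changed in both directions. Of 22 genes of cholesterol synthesis 9 were lower and 1, Insig1, higher (11 and 1 when adjusted over the list alone), with Hmgcs1, which makes the precursor of mevalonate, at 948 ± 96 against 455 ± 46, and Insig1, a brake on the pathway, 1.45-fold higher. The list's camera adjusted p = 0.0385 became 0.0669 as an adjusted p with TMM factors, an adjusted p = 0.514 with an estimated correlation, and was also lost without WT replicate C (adjusted p = 0.066) or KO replicate B (adjusted p = 0.0501). In the list of lipid efflux and fatty acid metabolism 13 of 26 were lower and 4, Apoe, Cd36, Lpl and Plin2, higher (14 and 6 when adjusted over the list alone; adjusted p = 0.381), and with TMM factors 8 were lower and 5 higher. Scd2, a fatty acid desaturase gene, was 5.01-fold lower and the cholesterol exporter gene Abcg1 1.79-fold lower, beside the rise of Apoe.

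Another 4 lists did not pass. Phagocytic receptors and complement had 7 higher and 11 lower of 27 (7 and 11 when adjusted over the list alone; adjusted p = 0.975): C3, the central complement component, rose 20.4-fold, and the lysosomal receptor gene Scarb2 was 1.89-fold lower. The median of that list was -0.07 and its mean 0.16. Lysosomal genes had 9 higher and 7 lower of 34 (9 and 9 when adjusted over the list alone; adjusted p = 0.57), and with TMM factors 11 higher and 2 lower; the cholesterol transporter gene Npc1 was 2.36-fold lower. The TGF-beta list had 4 higher and 9 lower of 19 (5 and 10 when adjusted over the list alone; adjusted p = 0.57), with Bambi, a decoy receptor, 4.22-fold higher and Eng, a co-receptor, 1.91-fold lower. The other 3 higher genes were Tgif1, Smad7 and Skil. Of 41 splicing regulators, proteins of the same function as QKI, 1, Hnrnpa1, was higher and 7 lower (1 and 3 when adjusted over the list alone; adjusted p = 0.969), and with TMM factors 4 higher and 3 lower. Khdrbs3, a STAR family relative of QKI, was 3.83-fold lower, from 1471 ± 175 to 384 ± 38.

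For another pair of lists the balance depended on the scaling. Actin and migration genes had 9 higher and 9 lower of 36 (11 and 10 when adjusted over the list alone; adjusted p = 0.0683), and 15 higher and 1 lower with TMM factors, where the list passed (adjusted p = 0.0111); it also passed without WT replicate B (adjusted p = 0.0478) or KO replicate B (adjusted p = 0.0197). The integrin gene Itga4 rose 7.20-fold there. Genes of oxidative phosphorylation had 5 higher and 5 lower of 35 (5 and 4 when adjusted over the list alone; adjusted p = 0.185), and 12 higher and 0 lower with TMM factors (adjusted p = 0.0224). The lower genes were Sdhc, Sdhb, Ndufb3, Ndufv1 and Ndufs1, calls that ended with TMM factors, and the higher ones Uqcrh, Cox4i1, Cox8a, Ndufa2 and Cox5a.

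All p-values of single genes are adjusted p-values from limma over 22472 genes, and those of lists are camera adjusted p-values over the 16 gene lists or the 13 marker lists. None of the lists passed with an estimated correlation between genes. The 8 gene lists that camera called also passed with fry, which does not compare a list with other genes. Their fry adjusted p ran from 0.000152 for the interferon response to 0.0147 for the cell cycle.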

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

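Leaving out libraries, the pseudocounts, filters, thresholds and list tests were planned; TMM factors, the tests on recovered reads or fragments, the letters as a block and the mean limit were chosen after the data were seen. The count of called genes ran from 6113 to 6732 (higher 2081 to 2254, lower 3859 to 4578) with each library left out. With TMM factors 3452 were lower, with edgeR 3418, with RLE factors 3354, with limma-voom 3164 and on fragments 3376, against 5252; 5863 genes were called by both edgeR and the deposited scaling, all in the same direction. An adjusted p under 0.01 left 4710 genes (2994 lower), and an absolute log2 fold change of at least 1 left 2936 (1199 higher, 1737 lower), as these thresholds must. With the column letter as a replicate block 9378 genes passed (3012 higher, 6366 lower), and no list gained or lost its call. The log2 fold change of Qk stayed between 1.06 and 1.15 with libraries left out and reached 1.23 with TMM factors, past the threshold in every setting run.

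With an estimated correlation the adjusted p rose to 0.126 for the interferon, NF-kB, antigen presentation and immediate early lists, 0.148 for the homeostatic list, 0.252 for disease-associated genes, 0.334 for the cell cycle and 0.514 for cholesterol synthesis. The cholesterol list ran from 0.0306 to 0.066 with libraries left out, and had 0.323 above the median level, 0.0669 with TMM factors, 0.0736, 0.0741, 0.0691 and 0.07 with edgeR (TMM, RLE, upper-quartile, fragments), 0.0715 with DESeq2 and 0.0867 with limma-voom. The actin list, at 0.0683, ran from 0.0197 to 0.193 with libraries left out, and had 0.0415 above the median level, 0.0111 with TMM factors, 0.0214, 0.0202, 0.03 and 0.03 with edgeR in that order, 0.0133 with DESeq2, 0.00991 with limma-voom and 0.0485 with fry. Oxidative phosphorylation passed with TMM factors (0.0224), edgeR (0.0379; RLE 0.0346), DESeq2 (0.0244) and limma-voom (0.0216), and not with edgeR on upper-quartile factors (0.0598) or fragments (0.052). With fry alone, which does not compare a list with other genes, the pathway lists of lipid efflux (0.00679) and TGF-beta (0.0127) passed. Among the marker lists, B cells (0.0406) and NK cells (0.0192) gained the call with fry. Border-associated macrophages (0.114) and pericytes and fibroblasts (0.0889) lost it. The cause of these changes was not tested. Of 2401 values of single named genes under other settings, 2363 kept their side of the threshold and direction, 37 lost the call, 1 gained it and 0 reversed; with single libraries left out, Sdhc, Ebf1, Klrb1c and Olig2 lost it and Cd4 gained it. Of 263 values of marker lists 222 kept their side, 11 lost and 30 gained the call. Genes under the median level have no value there. All 503 genes of the authors' deposited list passed in the same direction by limma, also at an absolute log2 fold change of at least 1, and with DESeq2.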

Other observations

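The tests on the exchange of columns and on neutrophil RNA, the symbol families and the comparison with other orders of the motif's letters were chosen after the results were seen. Genes of the cytosolic ribosome rose together in the libraries labelled KO. Of 87 protein-coding genes with ribosomal protein symbols, 83 were higher and 1, Rpl7l1, lower, with a median log2 fold change of 1.16, and with TMM factors 83 were higher and 0 lower. Rplp0 rose 2.52-fold (log2 fold change 1.33, SE 0.10) and Rpl3 1.86-fold (0.90, SE 0.08). Together these 87 genes took 1.37% to 1.69% of normalised reads in the libraries labelled WT and 3.29% to 3.66% in those labelled KO. Rows of their pseudogenes, which can share reads with them, were higher in 43 of 62. Of 78 genes of the mitochondrial ribosome 2 were higher and 15 lower (7 and 5 with TMM factors), and of 1127 other protein-coding genes in the same length range 168 were higher and 240 lower (median -0.09, and 0.05 with TMM factors).

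Other families, found by a search over 231 symbol roots, moved as groups. Among all 12896 genes compared, 1926 were higher and 4216 lower. Of 348 Zfp zinc finger genes 198 were lower and 10 higher (Fisher's exact test, adjusted p = 7.01e-19), and over 350 such symbols 131 were lower and 13 higher with TMM factors. The interferon-induced Ifi symbols were higher in 13 of 15 (Fisher's exact test, adjusted p = 1.6e-07), Cxcl chemokines in 7 of 9 (Fisher's exact test, adjusted p = 0.00258) and Snora small nucleolar RNAs in 10 of 23 (Fisher's exact test, adjusted p = 0.0314). All 12 Pcdhga and all 10 Ugt symbols tested were lower, with both scalings, but the members of these clusters share exons and their rows are not independent.

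Qk was higher in the libraries labelled KO, with a log2 fold change of 1.09. An exchange of the Control and Treatment columns would place the lower Cx3cr1, the locus of the Cre, in the columns named Control, whereas it was lower in all 3 Treatment libraries, with a log2 fold change of -2.08. That test was chosen after the result was seen, and Cx3cr1 is itself among the homeostatic genes that fell. Reads from outside the deleted part of the gene may account for a signal that remains, since the largest coding exon holds 5.1% of the counted transcript and its loss could be hidden. Such reads alone could keep the value near its level in the libraries labelled WT, not raise it. The value went from 11632 ± 800 to 24768 ± 1073 normalised reads (SD, n = 3 each). This argues against such reads as the cause of the rise. The test set beforehand could decide only where that exon held most of the transcript. The exon flanked by loxP sites is not given in the labels and reads per exon were not analysed here. Whether an exon was lost therefore stays open. An actual change in transcription or stability of Qk with the genotype was not tested.

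Neutrophil genes were lower in the libraries labelled KO. If RNA of neutrophils, which carry CD45 and CD11b and so could pass the gate, had entered the libraries labelled WT in unequal amounts, the log2 ratio of WT C to WT B would be about equal for all 11 markers. Its median was 3.24 and its SD 0.73, between the bounds set for and against, so the test does not decide. Over the 6 markers with a mean above 100, a set chosen afterwards, the SD was 0.15 around a median of 3.12. For WT A to WT B it was 0.21 around a median of 1.46 in that set. The other markers, Mmp8, Retnlg, Cxcr2, Ly6g and Mmp9, held only 0.9 to 5.3 normalised reads in WT B. Ratios to such low values are uncertain, which limits the SD over all 11. The most abundant marker, S100a9, reached 4626.3 normalised reads in WT C and at most 34.2 in a library labelled KO. Whether the gate on CD45 and CD11b removed neutrophils depends on the levels chosen, which are not given here. No gene of the list is in another list. A difference in cells that the genotype itself brought about was not tested.

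Markers of neurons, glia and vessels were lower in the libraries labelled KO. The common total of the columns is argued against as the whole cause, since with TMM factors the median over the 70 markers was still -1.29 (quartiles -1.64 and -0.89). Without WT C, the library with the most of these markers, it was -1.03. RNA of other brain cells carried through the sort was set against a broad low-level background of reads in the libraries labelled WT. The test set beforehand did not decide between them. Receptor genes of the nose, which brain cells hardly express, had a pooled log2 ratio of -0.36 (SE 0.09). This lay between the bounds of -0.3 and -0.5 set beforehand. Of 10 symbols with the root Olfr and a mean above 10, 1 was called higher and 3 lower, so the pool may not measure background alone. The pooled ratio used the deposited scaling. The TMM factors, 1.03 to 1.087 for WT and 0.943 to 0.973 for KO, would move it towards 0. That could take it past the bound of -0.3, to the side set for RNA carried through the sort. The ratio was not computed on that scale, so the outcome of this test may depend on the scaling. The pooled values of these 1438 receptor genes were 564.2 to 647.0 normalised reads in the libraries labelled WT and 425.2 to 490.0 in those labelled KO. In the same order, the 14 neuronal markers summed to 691.4 to 838.1 and 333.3 to 396.4. The 12 astrocyte markers summed to 7296.6 to 11614.3 and 3390.1 to 4473.4. Oligodendrocyte sums overlapped between the groups. A background spread evenly over genes would take far less from each gene than the neuronal and astrocyte sums lost. These values argue against it as the whole cause for those lists. The astrocyte sums lean on 1 abundant marker, Slc1a3. It had 5261 ± 650 normalised reads in the libraries labelled WT and 2223 ± 261 in those labelled KO (SD, n = 3 each). For its level it varied less between the libraries labelled WT than the astrocyte marker Slc1a2 did (1219 ± 536). A sort on CD45 and CD11b should remove the astrocytes that express Slc1a3. Whether the sorted microglia express it was not tested. None of the markers is in another list, but microglia may express some themselves, and how many do was not tested. A change that the genotype itself brought about was not tested either.

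A hypothesis of its own was that loss of QKI lowers transcripts whose 3' untranslated region holds its motif, ACTAAY with Y for C or T. Among 11659 coding genes with such a region, 1538 with 2 or more motifs were compared with 7591 genes without, matched on length of the region and mean level (matched difference -0.098, permutation p = 0.0001, the smallest that 10000 permutations can give). Of the 119 other orders of the same letters, 2 gave a lower difference, and their median was -0.026. The difference is consistent with the hypothesis, but it is small, genes are not independent, other orders also lay below 0, and the Qk count itself went up.

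The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real groups gave 7781 genes and the highest of the other splits 0, with 178 to 579 genes at an unadjusted p under 0.05 there; among the 4 splits that part all 3 letter pairs the other 3 also gave at most 0. Each other split keeps 2 libraries of a label together on either side, and so part of the difference between the labels, so its counts are not those of unchanged libraries. With that limit, camera at the preset correlation called 8 of the 16 lists for the real groups and 1 to 9 for the other splits, which neither supports nor excludes the list calls.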
